A study of Drosophila melanogaster with 3 samples.

How the data were processed

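Binding was measured by chromatin immunoprecipitation followed by sequencing in whole Drosophila melanogaster embryos of both sexes, aged 6 to 16 h per the source label. The fly line carries Sox100B with GFP at its C terminus, and the labels name Sox100B as the antibody target. Per the labels, chromatin was sheared by sonication to a range of 200 to 800 bp, and the 3 samples are biological replicates numbered 1 to 3. All 3 fall into 1 group, so there is no comparison between conditions. The labels disagree on a further point: the free-text description of each sample speaks of an input control, whereas the antibody field, the assay name and a separately listed control experiment describe an immunoprecipitation. The samples were taken as immunoprecipitates, and the control experiment was not analysed here. The age field holds a number that is no embryo age, so the collection window was taken from the source label.

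The authors deposited 5 lists of genomic regions on the dm6 assembly. One list of 30000 regions came from each replicate and one of 30000 from the replicates pooled; per the file headers these hold peaks together with background, made as input for the irreproducible discovery rate (IDR), a method that keeps regions ranked alike in replicates. The fifth list holds the 5683 regions that passed the authors' optimal IDR threshold and is called the IDR list here. Per the deposited file descriptions, each of the 4 lists of 30000 was also made from 1 further shared file of unstated content. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited signal value of each region is the peak caller's own, on a scale that is not stated, and it was used only to rank regions within a list. The −log10 q-value of each region was also taken as deposited. The deposited summit offset gave the summit position. The number of reads behind each region is unknown, so no interval that needs read depth is given. Intervals on shares of regions cover the counting of regions only.

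All 5 lists hold regions on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X alone. Every region end lay within the arm lengths of the reference sequence, which is release 6 of the genome. Genes were the 13945 protein-coding genes of Ensembl release 115 on these arms. A summit was assigned to the coding sequence first, then to a 5′ UTR, a 3′ UTR, an intron (the rest of a gene) or intergenic sequence, which here includes genes that code for no protein. A promoter summit lay within 1 kb of an annotated transcription start site (TSS). Weak regions, the comparator for location and chromosome, were the 5683 regions of lowest signal in the pooled list among the 21218 that lay over 500 bp from every IDR region; none had a signal above 51.7 or a −log10 q above 0.412.

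Sharing between replicates was tested with the 5683 strongest regions of each replicate, counting an overlap of 1 bp or more, against 1000 circular shifts of the replicate regions along each arm (one-sided permutation test). Signal ranks were compared by Spearman's rho across IDR regions, with no p-value because regions are not replicates. Shares of summits were compared by Fisher's exact test (two-sided), and the share on X by an exact binomial test (two-sided) that takes the share of weak regions as fixed. For sequence patterns, windows of 100 bp on each side of the summit were searched on both strands for 13 patterns. The comparator had the same GC distribution in 20 quantile bins. It is called GC-matched weak regions, or weak regions where patterns are compared. It was drawn from all 21218 pooled regions over 500 bp from every IDR region, so its signals could exceed 51.7. In each bin the regions of lowest signal were taken, so no random draw was needed, although a seeded draw had been planned. Within promoters this gave 2449 regions for 2477 IDR summits, so some bins ran out and took regions of any signal. The 26 arrangements of paired Sox sites had 0 to 12 bp between the sites. For 18 gene lists, a gene counted as having a peak when an IDR summit lay in its body or up to 1 kb upstream, and the number of such members was compared with 10000 random lists matched on gene length in 20 quantile bins (two-sided permutation test). 1 list symbol had no gene in the annotation. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Neighbouring regions are not independent, so p-values describe these regions and not further embryos; replicate means with SD (n = 3) stand beside them. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

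Groups, tests, gene lists, sequence patterns and the rule for named genes were set before the data were examined. The rule names Sox100B, the gene with the nearest TSS for each of the 20 IDR regions of highest signal, and up to 4 members per gene list with the strongest peaks. Genes outside it are said to be so. 1 gene that the rule names is not reported here. The alternatives tried were a stricter set of 2841 IDR peaks with the highest signal, other overlap rules, list lengths, promoter widths, motif windows and comparators, other ways to assign peaks to genes, and leaving out each replicate. Matching gene lists on intergenic length, keeping 1 summit per merged region, splitting motif tests by promoter, and testing the X share by Fisher's exact test with the weak regions as a sample were added after seeing the data.

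On simulated data with known answers, 60 percent of 5683 regions planted as shared came back as 60.9 percent. A promoter share of 40.0 percent was recovered as 40.0 percent. That checks only the counting of distances, because the positions were planted by their distance to a TSS. Sox cores planted in 5 percent of 5683 windows passed an unadjusted 0.05 in 99 of 100 runs, in 3 percent in 79 runs and in 2 percent in 50 runs. With none planted, 2 runs passed. Only runs with an odds ratio above 1 were counted. Both sets of windows were drawn at random from pooled regions away from IDR peaks, without the GC matching of the main test. With 13945 genes and no list raised, 1 of 100 runs called any list. Raising the chance of a peak 2 times was called in 40 of 100 runs for the ribosomal protein list and in 15 for the somatic gonad list of 12 genes, so modest differences in short lists would mostly be missed.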

Results

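Sox100B is a transcription factor of the group E Sox family, whose members bind DNA through an HMG box. Regions that co-precipitated with GFP-tagged Sox100B were mapped in whole embryos aged 6 to 16 h, in 3 biological replicates of 1 group. Each replicate list and the pooled list held 30000 regions, most of them background by design: a q-value under 0.05 was given to 8532 regions in replicate 1, 10358 in replicate 2 and 8146 in replicate 3. Read depth is unknown. The free-text description of the samples mentions an input control while the antibody and assay labels name a Sox100B immunoprecipitation, and the latter is followed here. The question the design allows is where these regions lie, how alike the replicates are, and which genes and sequences they mark.

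Most of the 20 strongest Sox100B-GFP peaks lay within 1 kb of a TSS, and all of them ranked high in every replicate. The IDR list held 5683 peaks with a median width of 464 bp, which together covered 2121 kb or 1.58% of the 6 arms. Its top peak, at X 12750799–12751701 in intergenic sequence, had a signal of 4635 and lay 5011 bp from the nearest TSS, that of CG4004. The second peak, at 2L 480539–481362, lay in an intron of ush, which encodes a cofactor of GATA factors, and 1384 bp from the TSS of cbt, a zinc finger gene; its signal was 4220. Among the next peaks were an intron of CG11050 (signal 4103), the start site of the nucleotide-sugar transporter gene Ugalt with its summit 27 bp from the TSS (signal 4020), and an intron of Trl, which encodes the GAGA factor, at 3L 14759278–14759819 (signal 3879). The wing vein patterning gene px, cu, and HmgZ, which encodes another HMG-box protein, followed with signals of 3506, 3414 and 3410. Further down the top 20 stood start sites of CG14100, CG31145, CG18428, Art3, mRpL41, Fkbp14, CG1602 and CG18549, each with a summit 99 to 198 bp from the TSS. CG11811, CG32772, CG13323 and chinmo, a zinc finger gene of neuronal development, had the nearest TSS of 4 peaks at larger distances, of 8050, 1268, 11952 and 12473 bp. The summit assigned to CG11811 in this way lay in an intron of another gene. Of these 20 peaks, 13 had their summit within 1 kb of a TSS, 8 lay in introns and 12 between genes, and all 20 ranked among the 40 strongest regions of every replicate.

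At the gene for the tagged protein itself there was 1 IDR peak. Sox100B occupies 3R 31065253–31083407 on the plus strand, and the peak spanned 3R 31064746–31064967 in the intergenic sequence upstream, with its summit 406 bp from the TSS. It had a signal of 553 and rank 1226 in the IDR list. The overlapping regions ranked 1729, 1279 and 1261 in replicates 1, 2 and 3. No match to the Sox core lay within 100 bp of its summit.

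**Figure D1:**
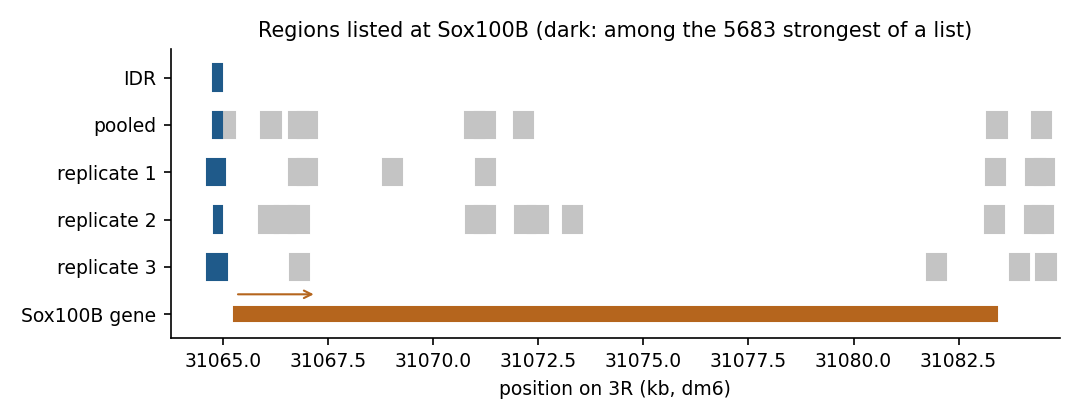
Regions of the 5 lists along the Sox100B gene on 3R (position in kb, dm6), with the gene drawn as a bar and its direction as an arrow. Regions among the 5683 strongest of their list are dark and lie only upstream of the TSS, whereas the regions inside the gene (light) rank lower.

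The replicates marked largely the same places. Of the 5683 IDR peaks, 4033 or 71.0% were overlapped by the 5683 strongest regions of all 3 replicates, 960 by those of 2, 608 by those of 1 and 82 by none. Shifting the replicate regions along the arms gave a mean of 0.0034% and at most 0.0528% (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). The share was 46.7% when an overlap had to cover 50% of both regions. With only the 2841 strongest regions of each replicate it was 40.3% of all 5683 IDR peaks, a share that the shorter lists hold down by construction. Of the 2841 IDR peaks with the highest signal, 98.8% were overlapped by the 5683 strongest regions of all 3 replicates. Single replicates covered 84.6%, 88.0% and 84.7% of the IDR peaks, with a mean of 85.8% ± 1.94 (SD, n = 3). Across IDR peaks, the signals of replicate pairs had Spearman's rho of 0.860 (1 and 2), 0.834 (1 and 3) and 0.863 (2 and 3), a mean of 0.852 ± 0.0160 (SD of 3 pairs); these are correlations across regions, which are not independent replicates. The IDR peaks are exactly the 5683 strongest regions of the pooled list, and the pool contains the reads of each replicate, so this sharing is not independent of the way the list was made. No region had identical coordinates in 2 replicates. The median width differed between their lists (450, 464 and 456 bp), so this does not show that the replicates are distinct.

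Sox100B-GFP peaks lay near gene starts more often than weak regions did, and less often in coding sequence. Summits within 1 kb of a TSS made up 43.6% of IDR peaks and 18.2% of the weak regions, an odds ratio of 3.48 with a 95% interval of 3.19 to 3.79 (Fisher's exact test, p = 6.8e-193). The strongest regions of single replicates gave 47.5%, 47.1% and 49.3%, a mean of 48.0% ± 1.19 (SD, n = 3), well above the weak regions. The median distance from summit to TSS was 1438 bp for IDR peaks and 4137 bp for weak regions. Coding exons held 0.422% of IDR summits against 2.90% of weak regions (adjusted p = 9.3e-27, Fisher's exact test) and 17.1% of uniform random positions. 3′ UTRs held 85 IDR summits against 271 summits of weak regions (adjusted exact p = 4.9e-24). Summits in 5′ UTRs were more frequent, at 5.01% against 3.54% (adjusted exact p = 0.00014), as were intergenic summits, at 38.6% against 34.7% (adjusted exact p = 2.4e-05). Introns held 54.4% and 54.1%, a difference that did not pass the threshold (adjusted exact p = 0.73). These location comparators were not matched on GC. Within 100 bp of the summit mean GC was 33.2% for IDR peaks, 36.7% for weak regions and 42.1% for random positions. How far base content accounts for the differences in location was not tested.

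**Figure D2:**
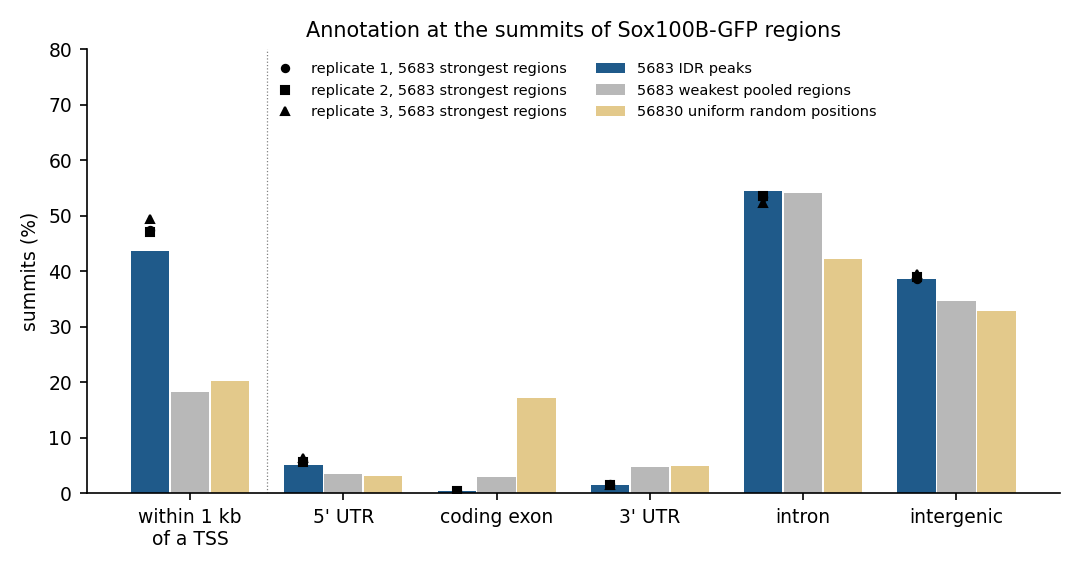
Percent of summits within 1 kb of a TSS (left of the dotted line) and in each of 5 annotation classes, for IDR peaks, weak regions and uniform random positions (bars) and for the strongest regions of each replicate (symbols). Promoter summits reach 43.6% in the IDR list and 47.1% to 49.3% in the replicates, against 18.2% of weak regions, and coding exons hold 0.422% of IDR summits.

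The Sox recognition core was not more frequent at these summits than in weak regions of the same GC content. ACAAWG, the core bound by HMG boxes of Sox proteins, lay within 100 bp of 24.9% of IDR summits and of 23.9% of GC-matched weak regions, an odds ratio of 1.05 with a 95% interval of 0.968 to 1.15 (Fisher's exact test, adjusted p = 0.37). The replicates gave 24.7% ± 0.490 (SD, n = 3). The difference was 0.985 percentage points, with an interval of −0.595 to 2.57. The 7-base form WWCAAWG gave an odds ratio of 1.08 (adjusted exact p = 0.16), and 3 patterns with the bases of the core in another order gave 1.04, 0.996 and 0.992. Group E Sox proteins can bind inverted site pairs as dimers, but of 26 arrangements of paired cores 0 passed the adjusted threshold and 0 had an unadjusted p under 0.05 (Fisher's exact test). Each arrangement occurred in at most 3 regions of either set, so this test had little power.

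Other sequence patterns did differ. The DNA replication-related element TATCGATA, the site of the promoter factor DREF, lay at 1.79% of IDR summits and 0.581% of weak regions, an odds ratio of 3.10 with an interval of 2.09 to 4.58 (Fisher's exact test, adjusted p = 2.3e-08). Within promoters alone its odds ratio was 2.05 (adjusted exact p = 0.00078), while at summits over 1 kb from every TSS it was 0.676 (adjusted p = 0.55). GAGAG, bound by the GAGA factor, was found at 19.2% against 16.0% (odds ratio 1.25, adjusted exact p = 3.8e-05), and WGATAR, the site of GATA factors, at 42.1% against 38.9% (odds ratio 1.14, adjusted p = 0.0029). At summits over 1 kb from every TSS their odds ratios were 1.24 and 1.22 (adjusted exact p = 0.0057 and 0.0013), and within promoters 1.16 and 1.04 (adjusted exact p = 0.29 and 0.73). The distal odds ratio over the promoter one was 1.07 for GAGAG (95% interval 0.882 to 1.30) and 1.17 for WGATAR (1.01 to 1.37, not adjusted for the 13 patterns). The E-box CAGCTG, a site of bHLH factors, was more frequent (odds ratio 1.24, adjusted exact p = 0.030) and the homeodomain site TAATTA less frequent (odds ratio 0.890, adjusted p = 0.030), but in the stricter set of 2841 peaks their calls and that of WGATAR were lost, with odds ratios of 1.17, 0.906 and 1.12 (adjusted exact p = 0.47, 0.32 and 0.15). The sites of Zelda and of forkhead factors and a CA repeat did not pass the threshold. For each of the 5 patterns that did, all 3 replicates lay on the same side of the weak regions as the IDR list. In each smaller set of IDR peaks selected without 1 replicate, TAATTA lost its call. Its odds ratios there were 0.920, 0.925 and 0.921 (adjusted exact p = 0.30, 0.27 and 0.30). The E-box lost its call without replicates 1 and 2 (odds ratios of 1.25 and 1.27, adjusted exact p = 0.064 and 0.051). These losses can reflect the fewer peaks in those sets.

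**Figure D3:**
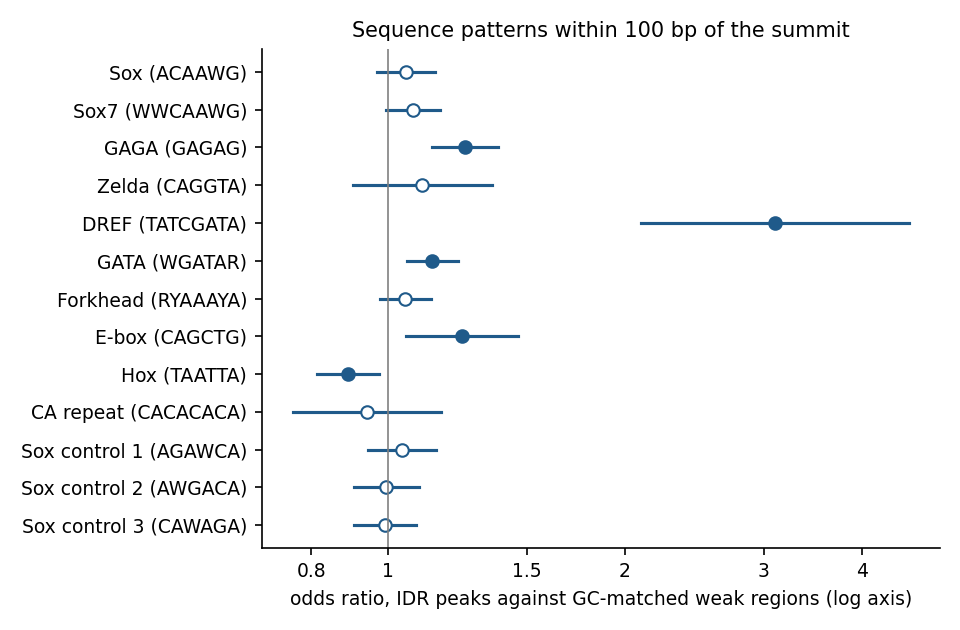
Odds ratios (log axis) of 13 sequence patterns within 100 bp of the summit, IDR peaks against GC-matched weak regions, with 95% intervals as lines. Filled points passed the adjusted threshold of 0.05; the Sox core (1.05) and its 3 reordered controls lie near 1, and the DREF site lies at 3.10.

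Genes for ribosomal proteins formed the only one of 18 lists whose excess of Sox100B-GFP peaks over length-matched genes passed the adjusted threshold. Of 85 genes for cytosolic ribosomal proteins, 61 had an IDR summit in the gene or up to 1 kb upstream, against 11.1 expected from genes of the same length, with 6 to 17 in the middle 95% of random lists (permutation test, p = 0.0002, the smallest that 10000 draws can give; adjusted p = 0.0036). The replicates marked 63, 65 and 70 of them. Among the strongest of these peaks were those at RpS27 (3R 25247276–25247925, summit 29 bp from the TSS, signal 1507), RpL34a (50 bp, signal 1382) and RpS10b (24 bp, signal 1286). Over all genes, 3106 of 13945 or 22.3% had a peak. The random lists were not matched on expression or promoter activity, and no mock or untagged list was analysed here. Whether the excess is specific to Sox100B is therefore not shown.

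No other list passed the threshold, so the counts that follow did not differ detectably from length-matched genes. Of the heat shock genes, 5 of 13 had a peak against 1.98 expected (unadjusted p = 0.069 and adjusted p = 0.62, permutation test), with the strongest at Hsp27 (signal 1472), Hsp83, the gene of the cytosolic Hsp90 chaperone (signal 1168), and the region shared by Hsp67Bc and Hsp22 (signal 466). The shared region was counted for both genes, and the random lists did not draw neighbouring genes together, so the p-values of the heat shock list take no account of this. The unadjusted permutation p was 0.016 in the stricter set (1.36 expected) and 0.039, 0.035 and 0.035 without replicates 1, 2 and 3, with adjusted p from 0.15 to 0.32. It was 0.26 with peaks given to the nearest TSS (4 of 13 against 2.03) and 0.21 with lists matched on gene and intergenic length (5 against 2.65), and 0.18 by Fisher's exact test without matching. For the remaining 16 lists the adjusted p was 1 by the same permutation test.

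Counts for genes of the gonad and gut depended on how peaks were assigned, their expected values depended on length matching, and none passed the adjusted threshold. In the somatic gonad list 6 of 12 genes had a peak against 5.08 expected, among them the posterior Hox gene Abd-B (signal 1111), the mesodermal homeobox gene tin (874), zfh1 (695) and the adhesion gene Fas3 (691). In the hindgut and Malpighian tubule list 6 of 12 had a peak against 4.60 expected, including fkh (1239), bowl (775), otp (593) and ct (405). In the midgut list 6 of 10 had a peak against 5.43, including the signalling gene dpp (637), pnt (564), peb (354) and Ptx1 (260). In the germ line list 2 of 11 had a peak against 3.40, at piwi (426) and vas (263). Counting only summits within 1 kb of a TSS lowered the counts to 3 for the somatic gonad, 2 for the hindgut and 3 for the midgut list, against 3.43, 3.43 and 3.38 expected. Giving each peak to the gene with the nearest TSS instead raised the somatic gonad count to 9 of 12 against 4.57 expected and the midgut count to 9 of 10 against 4.91 (permutation test, both unadjusted p = 0.014 and adjusted p = 0.083). Without length matching, 2.67 were expected for the somatic gonad and the hindgut list and 2.22 for the midgut list. Fisher's exact test then gave unadjusted p = 0.032, 0.032 and 0.011, each with adjusted p = 0.097.

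Lists of other tissues gave counts on either side of the expected values. The pan-neuronal gene elav had a strong peak upstream, with its summit 253 bp from the TSS (X 523263–523715, signal 1862, rank 102), and ChAT, Syx1A and Gad1 had weaker peaks in the gene or upstream (signals of 669, 218 and 210), in a neuronal list where 4 of 12 genes had a peak against 6.47 expected. The glial list had 4 of 10 against 3.02 (moody 647, Gs2 641, loco 487 and nrv2 174 in signal). In the muscle list 6 of 13 had a peak against 6.78, with the strongest at kirre (1064), Tm1 (746), rols (643) and Mef2 (627). Without length matching 2.89 were expected there (Fisher's exact test, unadjusted p = 0.049 and adjusted p = 0.13). The tracheal list had 4 of 11 against 4.75, with trh, which directs tracheal fate, at a signal of 1276, followed by rib (746), bnl (411) and knrl (186). The epidermal list had 4 of 11 against 4.67, at grh (805), nyo (403), tyn (346) and dyl (178). The haemocyte list had 2 of 11 against 3.92, at ush and lz (signal 175). The neuronal count fell to 2 without replicate 1 (5.74 expected) and without replicate 3 (5.71 expected), with unadjusted permutation p of 0.042 and 0.053 and adjusted p of 0.25 and 0.32. The haemocyte count was 1 whichever replicate was left out. These sets hold fewer IDR peaks, so such drops need not come from the replicate itself.

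Gene families and pathways also stayed short of the adjusted threshold. Among the 7 other Sox genes, Sox14 (2R 23978333–23978765, signal 1691, rank 132) and Sox102F on chromosome 4 (signal 1071) had peaks, against 2.62 expected. Of the 8 Hox genes 5 had a peak against 4.76, with Abd-B, Antp (847), Dfd (392) and pb (336) the strongest. Wnt pathway genes had 6 of 12 against 6.20, at arr (984), nkd (921), fz (814) and Wnt6 (483) among others. The JAK-STAT list had 2 of 8 against 2.66, at Stat92E (623) and Socs36E (544). The sex determination list had 3 of 10 against 2.99, at Sxl (682), dsx (599) and fru (335). The cell death list had 3 of 8 against 1.99, at Diap1 (812), hid (748) and p53 (473). With peaks given to the nearest TSS, 5 of 7 Sox genes were marked against 2.38 expected and 5 of 8 cell death genes against 1.87 (unadjusted permutation p = 0.082 and 0.032, adjusted p = 0.29 and 0.14). Without length matching, 1.78 were expected for the Hox list and 2.67 for the Wnt list (Fisher's exact test, unadjusted p = 0.017 and 0.032, both adjusted p = 0.097).

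**Figure D4:**
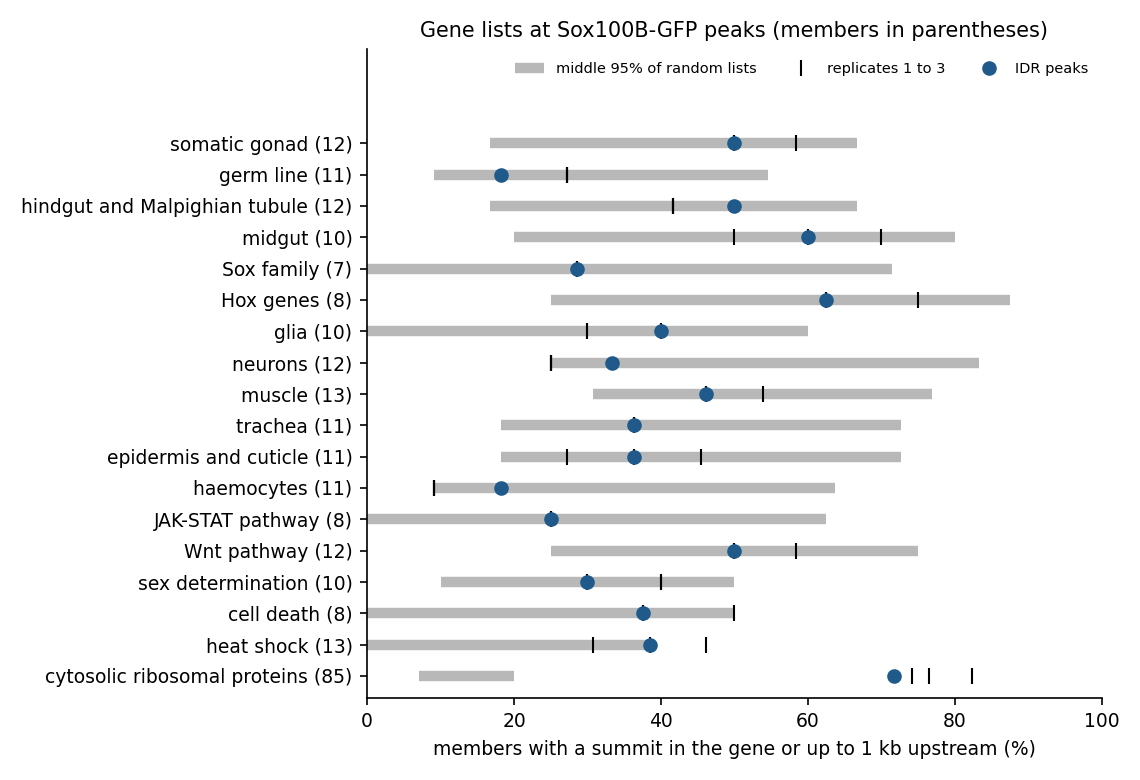
Percent of the members of 18 gene lists with a summit in the gene or up to 1 kb upstream, for IDR peaks (points) and the strongest regions of each replicate (ticks), with the middle 95% of length-matched random lists as grey bars. The ribosomal protein list, with 61 of 85 genes, lies outside its bar; the IDR points of the other 17 lie within theirs or at its end.

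The X chromosome held 1026 IDR peaks, or 18.1% (exact 95% interval 17.1 to 19.1). Weak regions had 16.6% on X, 944 of 5683. Taking that share as fixed, as planned, gave p = 0.0039 (exact binomial test), but counting the weak regions as a sample too gave an odds ratio of 1.11 with an interval of 1.00 to 1.22 and p = 0.045 (Fisher's exact test), which was lost without replicate 1 or 2. The X share was not distinguishable from the 17.6% of arm length that X makes up (exact binomial test, p = 0.36). Embryos of both sexes were used, so X has fewer copies than an autosome, and arm length takes no account of this. The replicates gave 17.8% ± 0.520 (SD, n = 3). The small chromosome 4 held 28 IDR peaks, or 20.8 per Mb, whereas the other arms held 36.7 to 47.2 per Mb; weak regions reached 133 per Mb there.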

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

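Peaks kept as 1 summit per merged region, gene lists matched on intergenic length, the settings for patterns other than the Sox core, the splits by promoter, and Fisher's exact test of the X share were chosen after seeing the data. The promoter excess kept its direction and its side of the threshold in all 8 alternatives, with odds ratios from 2.56 (against all 21218 pooled regions away from IDR peaks) to 4.66 (in the stricter set of 2841 peaks). Sharing by all replicates passed its permutation test in all its alternatives, with values from 40.3% (replicate lists of 2841 regions) to 98.8% (stricter set). The Sox core stayed short of the threshold throughout, with odds ratios from 0.990 (promoters alone) to 1.12 (window of 50 bp) and adjusted p from 0.12 to 1. The ribosomal protein list remained the only list called in each alternative, with 15.8 expected once matched on intergenic length.

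The stricter set lowered the number of peaks to 2841 by construction. Mean rho was 0.826 with summits required to lie within 100 bp and 0.877 in the stricter set, and single pairs ranged from 0.834 to 0.863 when each replicate was left out; the cause was not tested. The X share of 18.1% lost its call against arm length (p = 0.36, exact binomial test), because that comparator lies higher than the share of weak regions. With the weak regions counted as a sample it passed at p = 0.045 but not without replicate 1 (17.7%, p = 0.14) or replicate 2 (17.9%, p = 0.096, Fisher's exact test). Of 84 settings for the other patterns 67 kept their side of the threshold and 17 lost it: 7 for TAATTA, 6 for the E-box, 2 for WGATAR and 1 each for GAGAG and TATCGATA, whose odds ratio turned to 0.676 away from promoters. For named peaks, the effect of leaving out a replicate was largest at nrv2, whose mean percentile rank went from 73.1 to 82.4 without replicate 3. Read depth was unknown, so its effect could not be examined.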

Other observations

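The tests of the Sox core away from promoters and in the strongest peaks, and those of CACTG on other arms and by position, were chosen only after the result was seen, and the comparisons that decide them were revised after their first values. Genes in the next paragraph were picked after their values were seen and lie outside the rule for named genes, apart from kirre.

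The 15 genes with the most IDR summits held 229 of them, or 4.03%, and some of the 15 are named here. The largest number lay in kirre, which is needed for myoblast fusion, with 29 summits over 394 kb (X 2740384–3134532). That is 7.36 per 100 kb, against 4.24 over all arms. Far denser were shn, a mediator of Dpp signalling, with 20 summits in 58.3 kb (34.3 per 100 kb), and rdx, with 21 in 65.0 kb (32.3 per 100 kb). CG1677 had 18 summits, the Notch cofactor gene mam 13, the kinase gene Raf 13, the ecdysone-induced nuclear receptor gene Eip75B 15 and bun 15. Promoter summits whose nearest TSS belongs to a ribosomal protein gene lay a median of 41 bp from it, against 260 bp for other genes, and 23.5% of the 68 held the DREF site against 3.15% of the 2409 others. The Sox core lay at 13.2% (9 of 68) and 23.8% of these; neither difference was tested. IDR summits were also poor in GC: within 25 bp of the summit GC was 30.5%, against 43.9% at 300 to 400 bp, while weak regions went from 35.9% to 40.1%.

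The Sox core was no more frequent at IDR summits than in weak regions, and 3 explanations were tested. Weak regions holding Sox sites of their own is argued against by a comparison with GC-matched random noncoding positions, where the odds ratio was 0.963 (95% interval 0.884 to 1.05). Dilution of distal Sox sites by promoter peaks and dilution by weaker peaks stay open. The odds ratio was 1.10 (0.978 to 1.23) at summits over 1 kb from every TSS, 1.11 times (0.931 to 1.32) that at promoters, and 0.936 (0.774 to 1.13) in the 1136 strongest peaks, 0.878 times (0.709 to 1.09) that in the others. The 7-base form WWCAAWG gave 1.13 (1.02 to 1.26) at the distal summits, with an adjusted exact p of 0.098. The upper 95% bound of the difference in share over weak regions was 2.57 percentage points. Sites that differ from these patterns, recruitment through other proteins, and libraries that are input chromatin as the free-text label reads all stay open, since no control list was analysed here.

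The excess of promoter summits was set against 2 explanations. Weak regions being poor in genes is argued against by uniform random positions, which gave an odds ratio of 3.05 (2.88 to 3.22). Whether promoter chromatin was caught without a Sox site is left open: among promoter summits the odds ratio of the Sox core was 0.990 (0.868 to 1.13), but the core showed no detectable excess over all IDR summits either, so this value does not decide. The prediction written beforehand took the lack of a clear excess at promoters as favouring this explanation. It did not ask for an excess over all IDR summits, and that requirement was added later. Open chromatin of active promoters as a source of background stays open, because no mock or untagged list was analysed here, and no biological explanation was tested.

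A search of all 2080 words of 6 bases on 2L and 2R, made after the patterns above had been tested, found 41 words more frequent at IDR summits past the adjusted threshold (Fisher's exact test), led by ACAGTG and ACACTG, which share CACTG on one strand; the Sox words ACAATG and ACAAAG ranked 552 and 353. On the arms not used in the search CACTG lay at 39.0% of IDR summits and 23.9% of weak regions, an odds ratio of 2.03 (1.83 to 2.24), which argues against a chance find, and of the 59 other words with the same bases 0 had an odds ratio as high, the highest being 1.37, which argues against base content. On these same arms the odds ratio was 1.77 in promoters and 2.21 elsewhere, and the replicates gave 39.1% ± 0.955 (SD, n = 3). CACTG was not concentrated at the summit itself. Per bp, matches within 25 bp of IDR summits were 0.523 times (0.473 to 0.577) those at 50 to 100 bp over all 6 arms. On the arms not searched they were 0.502 times (0.442 to 0.569), compared with 0.846 times in weak regions. Loss of GC at the summit does not alone give so low a value, as the 59 words of the same bases ran from 0.602 to 1.04 with a median of 0.810 at IDR summits. Within 25 bp CACTG was still denser than in weak regions, at 16.9 against 12.8 per 100 regions per 100 bp. No biological explanation was tested, and the protein that binds such a site was not sought.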
